A study of Homo sapiens with 6 samples.

How the data were processed

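RNA was measured in 6 libraries of MCF-7 cells, 3 transfected with a miR-455-3p mimic and 3 with a control, 48 hours after transfection. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

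Each deposited file listed genes by Entrez gene number with an expected count, an FPKM value and a mean transcript length, per the file headers. The expected counts were estimated reads per gene as the authors deposited them, not normalized, and 30.53% to 30.63% of the values per library were not whole numbers. The FPKM values had been scaled by the authors to transcript length and library size, and were deposited with 2 decimals. The submitters' processing notes name Bowtie2, HISAT and RSEM without a version or a role. The genome build, the annotation release, the strandedness of the libraries and the read length are not given in the sources used here. The lowest FPKM listed in any library was 0.01, and a gene absent from a library's file was given a count of 0. Genes were listed at between 15447 and 15518 per library, 16821 in any library and 14347 in every library. A RefSeq gene table of assembly GRCh38.p14 gave symbols for 16788 of the gene numbers, and 33 had none.

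Totals ran from 9164533 to 9517864 expected counts per library. The 10 most abundant genes took 6.13% to 6.39% of the counts in control and 6.96% to 7.21% in mimic libraries. Pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 1.674 to 6.841 over genes, so that no library was treated as a copy of another. Pairs across groups gave 15.877 to 16.908.

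Expected counts were rounded to whole numbers before testing, as edgeR and DESeq2 need. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM factors of 0.989 to 1.005, the filterByExpr filter on low counts with a minimum count of 10, no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter removed 3594 genes and left 13227. The biological coefficient of variation was 5.58%. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Fold changes are mimic over control.

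Gene lists, 26 in all, were fixed before the data were examined and were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the lists. The same test was run with the correlation estimated from the residuals. In that run camera also takes its p from the residual degrees of freedom of the 6 libraries, which are few. A call lost in it is thus not due to correlation between genes alone. Seed sites were searched in the longest annotated 3' UTR of each gene, and in coding sequence, in GENCODE release 29 on GRCh38, with genes matched by Entrez number. A 3' UTR was found for 16461 of the 16821 genes, of which 13077 were tested. The 7mer-m8 site TGGACTG pairs with bases 2 to 8 of miR-455-3p, whose sequence GCAGTCCATGGGCATATACAC was matched to the MIR455 hairpin of the annotation. Genes with and without a site were compared by their median log2 fold change and by camera. Genes were also matched on 3' UTR length and GC content, with a standard error from 1000 bootstrap draws of genes, which treats genes as independent. In a scan made after the planned seed test, the log2 fold change was regressed on the presence of each possible heptamer in the 3' UTR, across genes, with terms for 3' UTR length and GC content. Genes are not independent replicates in that scan.

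The genes named were chosen by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM in the higher group and no overlap between groups. It also took up to 4 members of each list with the lowest p, every measured member of the reported miR-455 targets, up to 6 fallen genes with an 8mer seed site, and COL27A1, the host gene of the microRNA. Genes named outside the rule are marked as chosen after their values were seen.

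Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), RLE and upper-quartile factors, no filter, a mean of at least 1 CPM, the replicate number as a block, each library left out in turn, and an added fold threshold. The closing section gives their effect.

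The tests were tried on simulated data before use. In counts simulated for the mimic against control comparison over 13137 genes, 72.7% of 99 genes changed by 0.5 on the log2 scale and 93% of 100 genes changed by 1 were recovered, and 11 of 176 calls were false. A simulated shift of -0.1 in the seed site genes was measured as -0.101. In the heptamer scan over 13077 genes, a simulated shift of -0.1 gave a coefficient of -0.099. Reads of near-identical genes may have been split between copies, and the values of TARP, H2AC7, AKR1C1 and the readthrough gene PEDS1-UBE2V1 are uncertain for that reason. The mature microRNA was not analysed here.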

Results

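RNA was sequenced from MCF-7 cells, an estrogen receptor positive luminal breast cancer line, 48 hours after lipid transfection of a miR-455-3p mimic or a control. A mimic is a synthetic RNA that supplies a mature microRNA to the cell. Each group held 3 libraries. Totals were 9394485 to 9517864 expected counts in the control libraries and 9164533 to 9300164 in the mimic libraries. The comparison asked which transcripts differ when miR-455-3p is supplied to breast cancer cells.

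Most measured genes of DNA replication, mitosis, cholesterol synthesis and the ATF4 stress response fell in the mimic libraries. Camera called these 4 lists with a preset correlation between genes, and with an estimated correlation it did not (adjusted p = 0.1354 for both cell cycle lists, 0.2553 for cholesterol synthesis and 0.2413 for ATF4). The epithelial keratin KRT80 fell 4.77-fold, from 227.34 ± 11.41 to 47.87 ± 2.89 FPKM (SD, n = 3 each; adjusted p = 6.262e-12). ASCL1, a transcription factor of neural precursors, rose 4.09-fold, from 19.26 ± 4.07 to 79.21 ± 8.96 FPKM (SD, n = 3 each; adjusted p = 3.555e-09). Of 13227 genes tested with edgeR's quasi-likelihood test, 2255 were higher and 2587 lower in the mimic libraries. Changes were mostly small: 148 of the higher and 270 of the lower genes had an absolute log2 fold change of at least 1. The mimic and control values did not overlap in 6301 of the 13227 tested genes (47.6%), where chance gives 10% for 3 against 3.

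Among the largest falls, the chemokine CX3CL1 fell 8.61-fold, from 3.62 ± 0.22 to 0.43 ± 0.07 FPKM (SD, n = 3 each; adjusted p = 7.024e-09). NT5E, an enzyme of the cell surface that makes adenosine, fell 6.13-fold, from 10.23 ± 0.2 to 1.68 ± 0.23 FPKM (SD, n = 3 each; adjusted p = 2.865e-10). The cholesterol transporter NPC1L1 fell 5.28-fold, KLHDC7B 5.21-fold, the interleukin receptor antagonist IL1RN 5.15-fold and ANKRD1 4.95-fold. The Ras activator RASGRP1 fell 4.71-fold and RASSF5 4.24-fold. The readthrough gene PEDS1-UBE2V1 was 4.87-fold lower, but it shares reads with its component genes and its control SD was 8.31 around a mean of 12.34 FPKM. It was 2.96-fold lower without control replicate 3 and 8.39-fold lower without mimic replicate 2. The log2(FPKM + 1) scale understates the change of low genes such as CX3CL1, which fell by 1.69 on that scale.

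Among the largest rises, the cadherin CDH18 rose 4.47-fold, from 1.9 ± 0.16 to 9.04 ± 0.8 FPKM (SD, n = 3 each; adjusted p = 1.528e-09). The hormone gene PTHLH and the glycine receptor gene GLRA3 each rose 5.25-fold. SYP, a protein of synaptic vesicles, rose 4.03-fold from a low level, 0.82 ± 0.28 to 3.34 ± 0.36 FPKM. HMGCLL1 rose 4.9-fold, SPTLC3 4.71-fold and LRTM2 4.25-fold. TARP rose 5.46-fold and the histone gene H2AC7 7.07-fold, and both share sequence with other genes. H2AC7 was near the floor in the control libraries, and was not listed in control replicate 2, where it was set to 0. Its rise was 13.33-fold without control replicate 1 and 4.81-fold without control replicate 2. In the principal component analysis the first component, with 58.7% of the variance, separated the groups, and the second, with 14.4%, set control replicate 3 apart at -21.38.

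**Figure D1:**
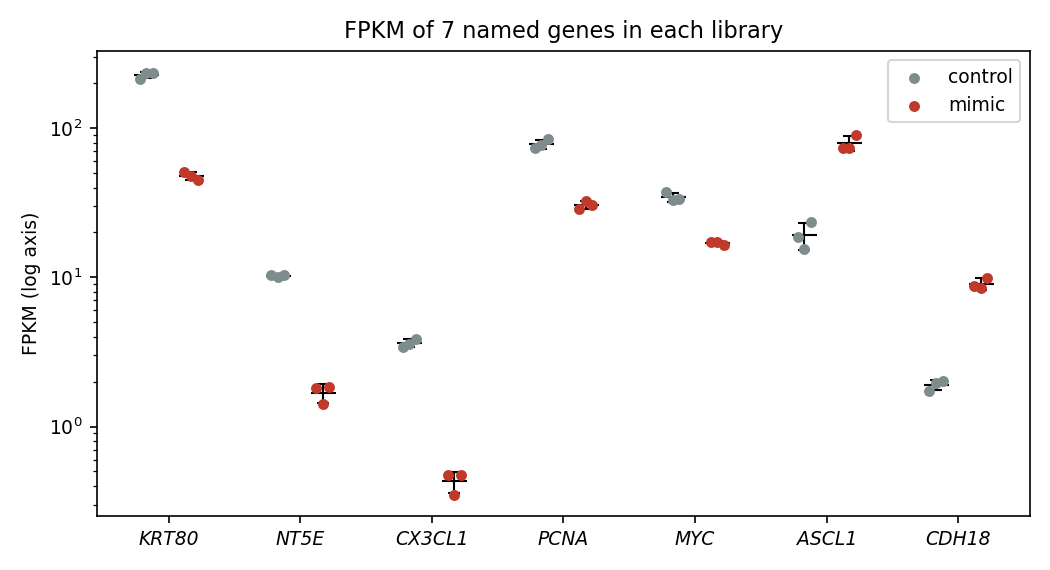
FPKM on a log axis of 7 named genes in each library, with points for libraries and bars for the mean and SD (n = 3 per group). KRT80, NT5E, CX3CL1, PCNA and MYC lie lower and ASCL1 and CDH18 higher in every mimic library than in every control library.

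In the list of G1/S and DNA replication genes, 21 of 23 measured members fell and none rose (22 fell when adjusted over the list alone). Their median log2 fold change was -0.57. PCNA, the sliding clamp of DNA polymerase, fell 2.56-fold, from 78.39 ± 5.47 to 30.71 ± 1.76 FPKM (SD, n = 3 each; adjusted p = 2.404e-09). E2F2 fell 2.15-fold, the helicase subunit MCM7 1.69-fold and the licensing factor CDT1 1.68-fold. In the list of G2/M and mitosis genes, all 24 measured members fell, with a median of -0.46. DLGAP5, a spindle protein, fell 2.37-fold, CDC20 1.62-fold, TPX2 1.52-fold and TOP2A 1.47-fold. Camera gave an adjusted p of 1.528e-11 for the first list and 1.11e-09 for the second. With an estimated correlation the adjusted p was 0.1354 for both.

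Of 20 measured cholesterol synthesis genes, 15 fell and 1 rose (camera adjusted p = 0.0001205). SQLE fell 1.4-fold, MVD and INSIG1 1.41-fold each and EBP 1.43-fold. Of 19 ATF4 stress response genes, 12 fell and 1 rose (16 fell when adjusted over the list alone; camera adjusted p = 0.0002578). The amino acid transporter gene SLC7A5 fell 2.29-fold, from 237.95 ± 9.67 to 104.3 ± 1.06 FPKM (SD, n = 3 each; adjusted p = 7.472e-10), and its partner SLC3A2 fell 1.53-fold. DDIT4 fell 2.2-fold, while the lipoprotein receptor gene VLDLR rose 1.6-fold. With an estimated correlation the adjusted p was 0.2553 for the cholesterol list and 0.2413 for the ATF4 list.

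Of 21 interferon response genes, 13 fell and none rose (camera adjusted p = 0.001897). OAS2, an enzyme of antiviral defence, fell 2.14-fold, from 181.19 ± 17.48 to 87.09 ± 15.11 FPKM (SD, n = 3 each; adjusted p = 5.822e-07). RSAD2 fell 1.87-fold, IFIT3 1.6-fold and IFIT2 1.54-fold. Of 9 NF-kB and inflammation genes, 5 fell and 1 rose (6 fell when adjusted over the list alone; camera adjusted p = 0.02222). TNF fell 2.05-fold, RELB 1.51-fold, ICAM1 1.47-fold and NFKB2 1.35-fold. The NF-kB call was lost without control replicate 3, with a camera adjusted p of 0.08457, and without the member that holds the heptamer GCATATA in its 3' UTR (0.06549), an alternative chosen after seeing the data. The list's median log2 fold change was -0.5569, and -0.5108 and -0.4975 in these 2 runs. With an estimated correlation the adjusted p was 0.6696 for both lists.

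Of 27 ribosomal protein genes, 7 rose and none fell, with a median of 0.15 on the log2 scale (5 rose when adjusted over the list alone; camera adjusted p = 0.00222). RPS27 rose 1.23-fold. Of 20 oxidative phosphorylation genes, 6 rose and 1 fell (camera adjusted p = 0.02826). COX6C, a subunit of cytochrome oxidase, rose 1.62-fold from 249.21 ± 21.66 to 406.91 ± 19.73 FPKM (SD, n = 3 each), NDUFA8 rose 1.26-fold and SDHA fell 1.19-fold. The make-up of the libraries differed between the groups too: the 10 most abundant genes took 6.13% to 6.39% of the counts in control and 6.96% to 7.21% in mimic libraries, and the MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA sequence, took 1.566% to 1.68% and 1.775% to 1.9%. The oxidative phosphorylation call was lost without control replicate 1 (camera adjusted p = 0.1048), without control replicate 2 (0.06681) and without mimic replicate 2 (0.0677). The list's median was 0.1025, and 0.0674, 0.089 and 0.1008 in these 3 runs, but 0.1669 without control replicate 3 (camera adjusted p = 0.001509). With an estimated correlation the adjusted p was 0.6696 for both lists.

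**Figure D2:**
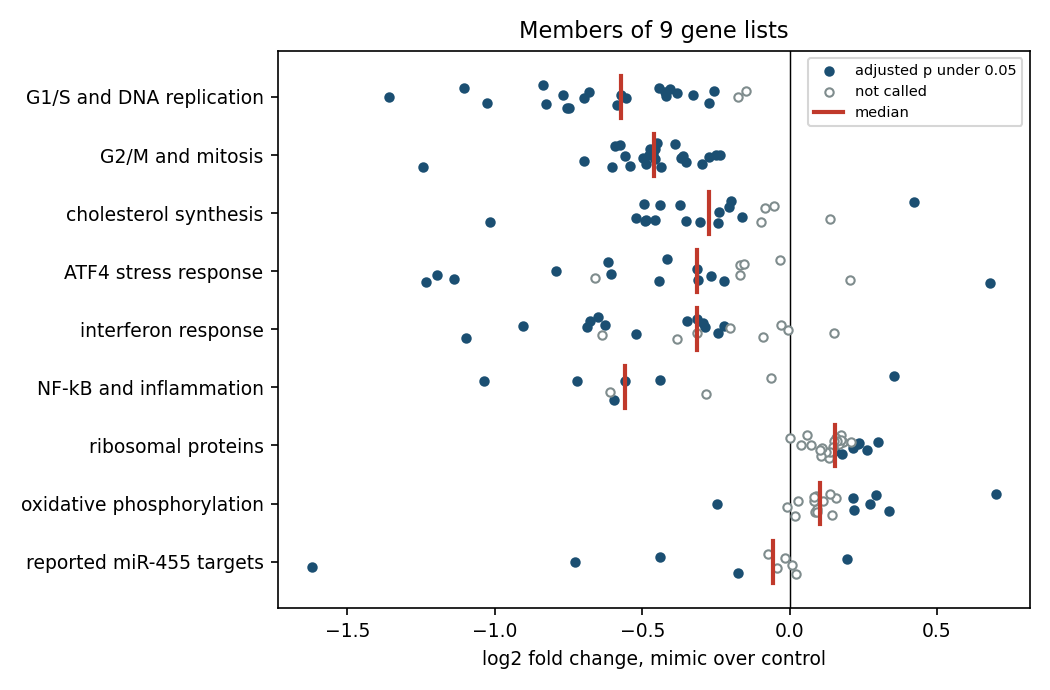
Log2 fold change, mimic over control, of each measured member of 9 gene lists. Filled points have an adjusted p under 0.05 in edgeR's test, open points do not, and red bars are list medians, from -0.57 for G1/S and DNA replication to 0.15 for ribosomal proteins.

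The remaining 18 lists did not pass the camera test (adjusted p = 0.08542 to 0.9678). Of 18 genes of MYC and ribosome biogenesis, 2 rose and 7 fell (camera adjusted p = 0.08542), and the list passed without control replicate 2 (0.04219). MYC fell 2.05-fold, from 34.61 ± 2.39 to 16.99 ± 0.51 FPKM (SD, n = 3 each; adjusted p = 2.668e-08), and the nucleolar protein NCL fell 1.61-fold. Of 16 TGF-beta and BMP response genes, 4 rose and 8 fell (9 fell when adjusted over the list alone; camera adjusted p = 0.1001), and the list passed without mimic replicate 3 (0.04736). TGFB1 fell 2.57-fold, the signal transducer SMAD3 1.86-fold and the receptor TGFBR1 1.69-fold, while ID2 rose 1.79-fold.

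Of 20 estrogen receptor response genes, 9 rose and 7 fell. The receptor tyrosine kinase RET rose 2.2-fold, from 59.01 ± 1.1 to 126.22 ± 9.94 FPKM (SD, n = 3 each; adjusted p = 3.08e-09), and the progesterone receptor gene PGR rose 1.68-fold. STC2 fell 1.71-fold and IGFBP4 1.56-fold. The list's median was 0.06, its mean -0.01 and its camera direction up, and with 1 library left out its median ran from 0.0308 to 0.1141. Of 17 epithelial and luminal markers, 4 rose and 4 fell (5 fell when adjusted over the list alone). ELF3 fell 1.28-fold and CLDN4 1.21-fold. The keratins KRT8 and KRT18 rose 1.24-fold and 1.2-fold, calls that limma on log2(FPKM + 1) did not make (adjusted p = 0.1308 and 0.1319). Of 6 measured mesenchymal markers, 2 rose and 1 fell (2 fell when adjusted over the list alone). SNAI1 rose 2.67-fold, ITGA5 rose 1.5-fold and TGFBI fell 2.2-fold.

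Of 15 NRF2 antioxidant genes, 5 rose and 3 fell. HMOX1, the heme oxygenase, rose 2.37-fold and AKR1C3 1.9-fold, while NQO1 fell 1.31-fold. Of 12 heat shock genes, 5 rose and 3 fell. DNAJB1 fell 2.62-fold, from 71.08 ± 3.8 to 27.3 ± 0.83 FPKM (SD, n = 3 each; adjusted p = 6.546e-10), HSPB1 fell 1.53-fold and HSPH1 rose 1.39-fold. The heat shock list had a median of 0.08, a mean of -0.06 and an upward camera direction, and with 1 library left out its median ran from 0.0446 to 0.1088. Of 15 ER chaperone genes, 5 rose and 2 fell, with SEL1L up 1.49-fold and HSPA5 up 1.25-fold. Of 20 hypoxia and glycolysis genes, 2 rose and 6 fell, with LDHA down 1.34-fold and SLC2A1 up 1.28-fold. That list had a median of 0.01, a mean of -0.06 and a downward camera direction, and with 1 library left out its median ran from -0.1431 to 0.0359.

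Of 17 autophagy genes, 4 rose and 3 fell. The kinase gene ULK1 fell 2.41-fold, from 43.99 ± 1.53 to 18.31 ± 1.05 FPKM (SD, n = 3 each; adjusted p = 7.472e-10), and BECN1 rose 1.47-fold. The list's median was 0.03, its mean -0.05 and its camera direction down, and with 1 library left out its median ran from -0.0098 to 0.0586. Of 14 core apoptosis genes, 2 rose and 3 fell, with MCL1 down 1.52-fold and BAK1 down 1.53-fold. Of 20 p53 targets, 3 rose and 5 fell (4 rose when adjusted over the list alone), with TP53INP1 down 1.72-fold and GDF15 up 1.31-fold. Of 14 ERK feedback genes, 3 rose and 3 fell, with IER3 up 1.93-fold and DUSP5 down 2.37-fold. That list had a median of 0.09, a mean of -0.01 and an upward camera direction, and with 1 library left out its median ran from -0.035 to 0.1887. Of 13 genes of the microRNA machinery, 1 rose and 3 fell, with AGO4 down 1.57-fold and DGCR8 down 1.22-fold.

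Mean levels of the measured markers of other cell types in control libraries ran from 0.12 FPKM for VWF to 10.96 FPKM for LYZ, an immune marker. Further markers on these lists did not pass the filter on low counts or were not listed. Of 8 measured basal breast markers, 1 rose and 4 fell, with KRT17 down 2.75-fold from 7.97 ± 1.61 to 2.92 ± 0.57 FPKM (SD, n = 3 each) and EGFR down 1.72-fold. Of 6 fibroblast and endothelial markers, 1 rose, VWF, from 0.12 ± 0.03 to 0.25 ± 0.03 FPKM (SD, n = 3 each). That call was lost without control replicate 2 (adjusted p = 0.06632), without mimic replicate 1 (0.06154), with DESeq2 (0.06501) and with limma on log2(FPKM + 1) (0.1444). None of 4 immune markers was called.

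Of 10 measured genes reported elsewhere as miR-455 targets, 4 fell and 1 rose (camera adjusted p = 0.1702). RUNX2, a transcription factor of bone formation, fell 3.07-fold, from 2.12 ± 0.32 to 0.68 ± 0.1 FPKM (SD, n = 3 each; adjusted p = 3.026e-06). Of the 4 that fell, RUNX2 alone holds no 7mer-m8 seed site in its 3' UTR. The activin receptor gene ACVR2B fell 1.66-fold and SMAD2 1.36-fold. PAK2 was 1.13-fold lower (adjusted p = 0.02173), a call lost without each library but control replicate 3 (adjusted p = 0.05316 to 0.08502). APP, the amyloid precursor gene, rose 1.15-fold, a call lost without mimic replicate 1 (0.07123) and without mimic replicate 2 (0.06197). HDAC2, HDAC8, HSF1, EI24 and UBE2B were not called, with log2 fold changes of -0.07, -0.04, -0.02, 0.01 and 0.02. Of these, HDAC2, HDAC8, HSF1 and EI24 also hold the 7mer-m8 seed site, so the site did not set the fallen genes apart. UBE2B and APP hold none. COL27A1, which hosts the microRNA gene, was at 3.74 ± 0.61 FPKM in control and 4.15 ± 0.4 in mimic libraries (SD, n = 3 each; adjusted p = 0.3191).

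The seed site comparison asked whether genes with a site for the transfected microRNA differed as a set. The 1751 genes with a 7mer-m8 site in the 3' UTR had a median log2 fold change of -0.039, against 0.013 in 11326 genes without one, and the set was not called (limma's camera p = 0.1349, and 0.2491 with an estimated correlation). Of the genes with a site, 25.5% fell and 15% rose. Of those without, 18.8% fell and 17.5% rose. Genes that hold the 7mer-m8 site and rose include SPTLC3 (4.71-fold), RET (2.2-fold) and ID2 (1.79-fold). The 521 genes with an 8mer site had a median log2 fold change of -0.041, against 0.008 in 12556 genes without one. Camera did not call that set either. The difference in medians was -0.049 for 8mer and -0.052 for 7mer-m8 sites, so it was no larger for the 8mer. The 8mer genes named next were taken only from those that fell. Among genes with an 8mer site, PLAU, the urokinase protease, fell 3.7-fold, from 8.04 ± 0.99 to 2.19 ± 0.09 FPKM (SD, n = 3 each; adjusted p = 3.632e-08). Its 8mer lies in the 3' UTR on chromosome 10, with the heptamer at 73916826 to 73916832 (GRCh38, plus strand). CBFB fell 2.85-fold, with its site on chromosome 16 at 67100244 to 67100250 (GRCh38, plus strand). SENP1 fell 2.67-fold, FMNL2 2.54-fold and TNFRSF10A 2.43-fold. CBFB, SENP1 and TNFRSF10A also hold the heptamer GCATATA, described below, so their falls cannot be credited to the seed site alone. ALX3 was 2.36-fold lower (adjusted p = 0.01489), a call lost without control replicate 2 (0.0659), without mimic replicate 1 (0.08366) and without mimic replicate 2 (0.05196).

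Another heptamer, GCATATA, marked genes that were lower. It was chosen after the values were seen, as the lowest by t in the scan of all possible heptamers on these same fold changes. The 1341 genes with it in the 3' UTR had a median log2 fold change of -0.161, against 0.021 in 11736 genes without it (camera p = 3.7e-08, and 0.04535 with an estimated correlation). Of these genes 40.3% fell and 9.7% rose, against 17.3% and 18% of the others. Both camera p-values are unadjusted for the choice of the lowest heptamer, so neither can be read as a test of GCATATA. NT5E holds it in the 3' UTR on chromosome 6 at 85495545 to 85495551, and RUNX2 on chromosome 6 at 45547382 to 45547388 (GRCh38, plus strand). PCNA holds it in the 3' UTR on chromosome 20 at 5115216 to 5115222 (GRCh38, minus strand). DLGAP5, OAS2, DNAJB1, ULK1, MCL1, NQO1, SMAD2, CBFB, SENP1, TNFRSF10A, RASGRP1 and RASSF5 hold it too and fell, as do GLRA3, VLDLR and PGR, which rose. EI24 and ITGAM also hold it and were not called in edgeR's test (adjusted p = 0.9368 and 0.06182).

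**Figure D3:**
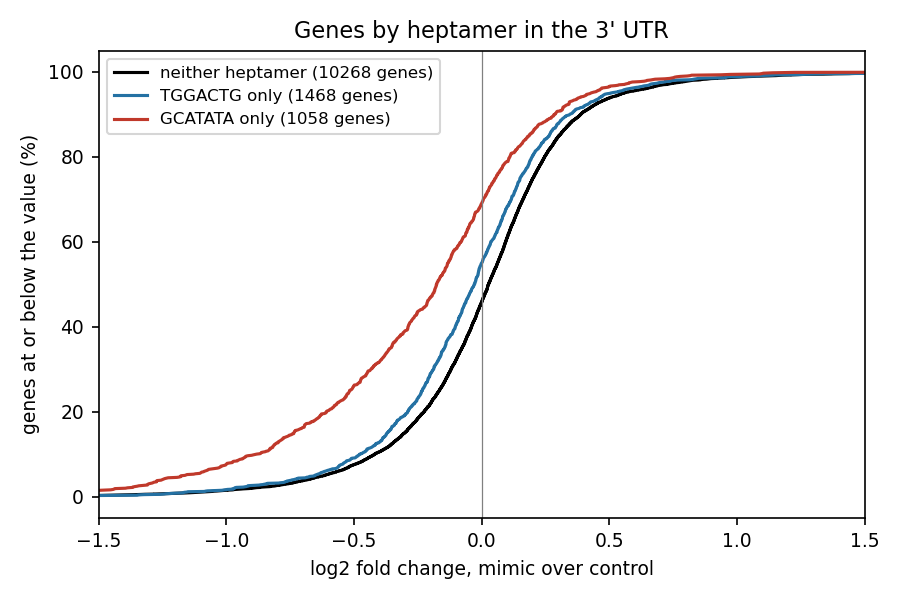
Cumulative percentage of genes by log2 fold change, mimic over control, for genes with neither heptamer in the 3' UTR (10268), with the seed site TGGACTG only (1468) and with GCATATA only (1058). The medians were 0.027, -0.029 and -0.176, and the horizontal axis is limited to -1.5 to 1.5. The 283 genes with both heptamers, with a median of -0.086, are not drawn.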

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

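The mean transcript length that the files give for each gene was used in no comparison of the report, and its test was chosen after the data were seen. It changes between libraries when the estimated mix of a gene's transcripts changes. Among 2326 genes with at least 50 expected counts in each library and a varying length, limma called 4 between mimic and control libraries (188 at an unadjusted p under 0.05), and none in the other splits of the samples. Those splits mix mimic and control libraries in both groups, which by itself lowers the number of calls. KALRN, a guanine nucleotide exchange factor, had a longer mean transcript, 5348 ± 163 against 4534 ± 27 bases (SD, n = 3 each; adjusted p = 0.04652). AIG1 was longer, at 2028 ± 14 against 1752 ± 50 bases, and so was PARP9, at 4017 ± 67 against 3631 ± 29 bases. GPATCH2L was shorter, at 4326 ± 26 against 4819 ± 76 bases. The adjusted p of all 4 lies just under the threshold. No explanation was tested.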

How the results depend on the processing

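No gene called in the main test had the opposite direction among the calls of any alternative run. The counts of higher and lower genes were 1668 and 2093 with DESeq2, 2257 and 2567 with limma-voom, 2222 and 2305 with limma on log2(FPKM + 1), and 2533 and 2376 with upper-quartile factors. With an absolute log2 fold change of at least 1 they were 148 and 270, by construction. Leaving out each library in turn gave 1584 to 2719 higher and 2033 to 2895 lower genes, the most without control replicate 3. Counting only genes with neither heptamer in the 3' UTR, an alternative chosen after seeing the data, left 1691 lower and 1879 higher genes. The genes left out fell more often than they rose (40.3% against 9.7% of genes with GCATATA, and 25.5% against 15% of genes with the seed site). Of the 8 lists that passed camera, 0 passed with an estimated correlation, and 7 or 8 of them passed when each library was left out. Counting lists that did not pass in the main run, 7 to 9 passed. The estimated correlation was 0.682 for the interferon list and 0.052 for the mitosis list. That run also uses fewer degrees of freedom, which raises p as well. For the seed site genes the estimated correlation was 0.0125, near the preset 0.01, and camera p went from 0.1349 to 0.2491. The seed site difference stayed between -0.0656 and -0.0412 when each library was left out, with camera p from 0.05297 to 0.2078. Of 137 named genes, 115 stayed on their side of the threshold in each alternative run for them, as did 16 of the 26 lists. The lists were not run with DESeq2, limma-voom or limma on FPKM, and H2AC7 has no value with a mean of at least 1 CPM, which it did not reach.

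The labels give both groups replicate numbers 1 to 3 without saying that a number marks a shared culture or day. The deviations of same-numbered libraries from their group means correlated, across genes, at 0.015, 0.154 and 0.123, and the numbers were not taken to pair the samples. Every library correlated best with its own number, though at only 0.015 for number 1. Deviations within a group sum to 0, so these correlations constrain each other. How often such a match arises by chance was not worked out. It is at most a weak hint from the data and not from the design. With the replicate number as a block, 2248 genes were higher and 2561 lower, 8 lists passed, and the seed site difference was -0.052. Of simulated changes of 0.5 on the log2 scale, 22 of 49 were recovered in genes with a mean count below the median of 300, and 50 of 50 above it.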

Other observations

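The tests of the heptamer GCATATA, and the tests of what accounts for the fall of the cell cycle lists, were chosen after the results were seen, as were the 2 added gene lists. The cell cycle lists themselves, the run without control replicate 3 and the tests of the seed site and of other splits were planned.

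In a scan of all possible heptamers in 3' UTRs, GCATATA had the lowest coefficient by t, -0.252 (SE 0.0123) on the log2 scale across genes, with CATATAA next at -0.1266 (SE 0.0117). Genes with 1 copy had a median log2 fold change of -0.142 and genes with 2 or more copies -0.276, against 0.021 with 0 copies. GCATATA pairs with bases 4 to 10 of the full complement of miR-455-3p. Of the 15 heptamer windows along that complement, this was the lowest, as its choice from all heptamers had fixed. Its neighbours CATATAC and GGCATAT were at -0.0738 and -0.0717. They share 6 bases with GCATATA, and genes that hold GCATATA are not left out of their coefficients. In genes without GCATATA, CATATA followed by C was at -0.0157 (SE 0.0157). The seed site of miR-455-5p, the natural opposite arm, had a coefficient of 0.0058 (SE 0.0118). A strand complementary to the mimic that begins at the third base of the full complement would have bases 4 to 10 of that complement as its own bases 2 to 8. The make-up of the mimic's second strand is not given in the sources used here.

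A hypothesis is that such a complementary strand may act on these genes as a microRNA does. It predicts that an A after the site adds to the fall. In genes without GCATATA, CATATA followed by A was lower than CATATA followed by C, G or T by a contrast of -0.0773 (SE 0.0163). That is the predicted direction. The coefficients were -0.0697 for A, -0.0157 for C, 0.0488 for G and -0.0104 for T, so the rise with G adds to the contrast. The prediction was written after the scan had placed CATATAA next to GCATATA. Its outcome was thus partly visible beforehand, and it is no independent test of the hypothesis. Against genes matched on length and GC content of the 3' UTR, the median difference was -0.196 (bootstrap SE 0.0175). The scan that chose GCATATA already had terms for both, so this is no independent test of them. Among 417 other orders of the same bases that share no run of 6 with GCATATA, the lowest was ATGCATA, at -0.0652 (SE 0.0117). GCATATA had been chosen as the lowest of all heptamers, so only the size of that gap was open. AGCATAT, which shares a run of 6 bases with GCATATA, reached -0.0951 (SE 0.0119). A control that lowered these genes through this heptamer would leave them higher in mimic libraries. The matched difference of -0.196 has the opposite sign, which argues against that. Another effect of the control's own sequence, or of an endogenous microRNA with the same seed, stays open. No untransfected library was used here and small RNA was not analysed here.

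For the planned seed site, the difference against genes matched on length and GC content was -0.045 (bootstrap SE 0.0121), so these do not account for all of it. It ranked 447 from the lowest of all heptamers by t, and 1348 by coefficient, both outside the lowest 163 (1%), so a shift of this size may arise with heptamers unrelated to the mimic. Camera did not call the set, and an effect of the mimic strand through this site stays open.

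In the 2 cell cycle lists, 5 of the 45 members that fell (11.1%, exact 95% interval 3.7% to 24.1%) hold GCATATA or the seed site in the 3' UTR. The fall of these lists is therefore not accounted for by sites of either kind in the 3' UTRs of most members. Sites in the members' coding sequence were not counted. Across genes without GCATATA in the 3' UTR, the 404 with it in coding sequence had a coefficient of -0.0875 (SE 0.0196). Control replicate 3 does not account for the fall of the lists: without that library the higher of the list medians was -0.454. Slower proliferation at the time of sampling remains a candidate explanation, which no measurement here tests.

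2 gene lists were written after some of their members had been seen, and those members were left out of the tests. They were ASCL1, SYP, VGF, STMN3 and RET for a neuroendocrine list, all of which rose, and CCN2, ANKRD1 and NT5E for a YAP and TEAD list, all of which fell. VGF (2.59-fold), STMN3 (2.61-fold) and CCN2 (2.41-fold) are named after their values were seen. Of the other 8 measured neuroendocrine genes, none rose and 1 fell, ENO2, named after its value was seen. Camera gave an adjusted p of 0.799 with a downward direction, so no rise of the list beyond the 5 genes already seen was found. Leaving out members that had risen tilts the rest away from a rise, so this is only weak evidence against one. Of the other 16 measured YAP and TEAD target genes, 9 fell and none rose, with a median of -0.24 (camera adjusted p = 0.007915, and 0.2197 with an estimated correlation). Among them TGFB2, named after its value was seen, fell 3.15-fold. A lower YAP and TEAD output is a hypothesis, since the list was prompted by genes seen in these data and its call is lost with an estimated correlation.

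The real grouping of the samples called 4842 genes and the highest of the other splits called 0. Each other split puts mimic and control libraries in both groups. The difference between mimic and control then widens the spread within groups, so a low count follows from the design and decides nothing. Only 1 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05.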
